A study of Mus musculus with 3 samples.

How the data were processed

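RNA was measured in granulocyte progenitors purified by flow cytometry from mouse bone marrow, in 3 libraries with 1 per group (NTB, 4T1-TB and IRF8-deficient), and each sample was placed in its group by the mouse model given in its labels. Per the labels' protocols total RNA was extracted with TRIzol and libraries followed the standard Illumina protocol. The number of mice behind each library is not given in the sources used here, nor are the read length, the strandedness and the kit. The deposited values are RPKM, reads per kilobase of gene model per unit of library size, made by the authors for 24421 gene symbols in each library. The submitters' processing notes name CASAVA 1.8.2, cutadapt 1.2.1, TopHat2 2.0.13, Picard 1.97, HTSeq 0.6.1 and edgeR 3.12.1 with the genome build mm10, and do not say what each tool did. The gene annotation, any filter and the form of the library sizes are not given in the sources used here. RPKM from the authors was used as deposited for the main values.

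The deposited RPKM of a gene in different libraries stood in ratios of whole numbers, so whole reads were recovered for the 15158 genes above 0 in any library. At the library size chosen to make this share largest, implied gene lengths were whole, up to rounding, for 92.6% of genes with enough reads. Of 14401 genes with a reference exon length, 91.7% were within 0.8 to 1.25 of it. Where a length was first far from its reference, reads and length could be multiplied by a factor chosen from that reference. Neither share is thus a fully independent check. Reference lengths and coordinates came from GENCODE M21, which is on the mm10 assembly. The library sizes implied by the deposited RPKM were 1.06 times the summed recovered reads in NTB, 0.956 times in 4T1-TB and 0.730 times in IRF8-deficient, and the product of these factors was 0.742. The reason for that difference is not given in the sources used here. At the median gene length of 2952 bases 1 read corresponded to an RPKM of 0.0076 in NTB, 0.0153 in 4T1-TB and 0.013 in IRF8-deficient, so an RPKM of 1 rested on 132.2, 65.6 and 77.1 reads. Ratios between libraries carry exact binomial (Clopper-Pearson) intervals and single levels carry exact Poisson intervals, both at 95% and both for counting error only. Where a library held 0 reads, the floor for a fold was 3 reads in that library. Recovered reads served for depth, intervals, floors and alternatives.

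Differences were taken on log2(RPKM + 1), which understates the difference of low genes, over the 10658 genes with an RPKM of at least 1 in 1 or more libraries, and a gene was called higher or lower at a difference of 1 or more in size. With 1 library per group there was no statistical test. For each gene list the median difference was set against 10000 random lists of the same size matched on mean expression in 20 bins, and the range from their central 95% is printed. This is a description of these libraries. The 34 lists comprised 21 of myeloid and metabolic function, 9 of other cell types and 4 of library quality or strain. Lists with under 3 members compared are given by value. Mitochondrially encoded genes had no member among the symbols compared. The comparisons, the calls, the lists and the rule for naming genes were fixed before the data were examined. That rule named Irf8, the 10 genes with the largest difference each way per comparison among those with an RPKM of at least 5 (leaving out predicted genes, pseudogenes, receptor segments, histones, ribosomal proteins and small RNAs), up to 4 members of each list, 10 genes each way that differed in both comparisons with NTB, and 20 fixed genes. Rn45s, Cxcr2 and the genes near 0 in 1 library were named after their values were seen.

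Because both comparisons with NTB share 1 library, unchanged libraries were simulated 20 times at each assumed biological coefficient of variation (0, 0.1, 0.2, 0.25, 0.3 and 0.4) with the mean levels and library sizes of the data. The values 0.25 and 0.3 were added after the first simulations were seen. The alternatives fixed at the start were pseudocounts of 0.1 and 5, median ratio scaling, rescaling without the 20 highest genes, no filter, an RPKM of at least 5, and a call at 4-fold. Scaling by summed recovered reads, thinning to equal depth and a call that also needs a counting interval excluding 1 were added after the data were seen.

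The steps were tested on simulated data for 4T1-TB against NTB with 15158 genes, 200 of them changed. Reads were recovered exactly for 98.9% of genes. All genes changed 4-fold, 0.25-fold and 2.5-fold were called (100% each) and 98% of those changed 0.4-fold, and 4 of 10148 unchanged genes were called. These simulated libraries held counting error only, so that number does not cover variation between animals. Of 500 unchanged lists 6.4% fell outside the central 95% of random lists. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.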

Results

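Gene expression was measured by RNA sequencing in granulocyte progenitors, the bone marrow precursors committed to making granulocytes, which were sorted by flow cytometry from female mice. The 3 libraries were 1 from non-tumor-bearing control mice (NTB), 1 from mice carrying 4T1 mammary carcinoma cells implanted at the orthotopic site (4T1-TB), and 1 from mice deficient in IRF8 (IRF8-deficient), a transcription factor that promotes monocyte and dendritic cell development and restrains neutrophil production. The NTB and 4T1-TB mice were F1 animals with the H-2b/d haplotypes and the IRF8-deficient mice were C57BL/6, so strain and genotype changed together in every comparison with the IRF8-deficient library. The study's title names the granulocyte progenitor as a stage at which IRF8 controls the output of myeloid-derived suppressor cells, the immature myeloid cells that accumulate in tumor-bearing hosts and dampen T cell responses.

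There were no replicates, so no difference below was tested against a spread between animals and no p-value is given. Each difference describes 3 libraries. The reads recovered from the deposited values came to 42080936 for NTB, 23239450 for 4T1-TB and 35782419 for IRF8-deficient, and 10658 genes reached an RPKM of 1 in at least 1 library. The ribosomal RNA precursor Rn45s, a gene singled out after its values were seen, took 1.8% of the reads in NTB, 6.36% in 4T1-TB and 13.8% in IRF8-deficient. The 20 highest genes took 9.92%, 15.1% and 29.5%. Intervals on single genes are 95% intervals for counting error only.

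Irf8, the gene after which the deficient mice are labelled, was examined first in every library. It lies on the plus strand of chromosome 8 of mm10, from 120736358 to 120756694 (ENSMUSG00000041515.10). Its RPKM was 43.8 in NTB (interval 42.7 to 44.8), 8.61 in 4T1-TB (7.96 to 9.29) and 13.7 in IRF8-deficient (13 to 14.5). Irf8 was thus 5.09-fold lower in the tumor-bearing library and 3.18-fold lower in the deficient library than in NTB. Transcript remained in the deficient library, at 1.6 times the 4T1-TB level (interval 1.45 to 1.76), and values per gene do not show which exons it came from.

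**Figure D1:**
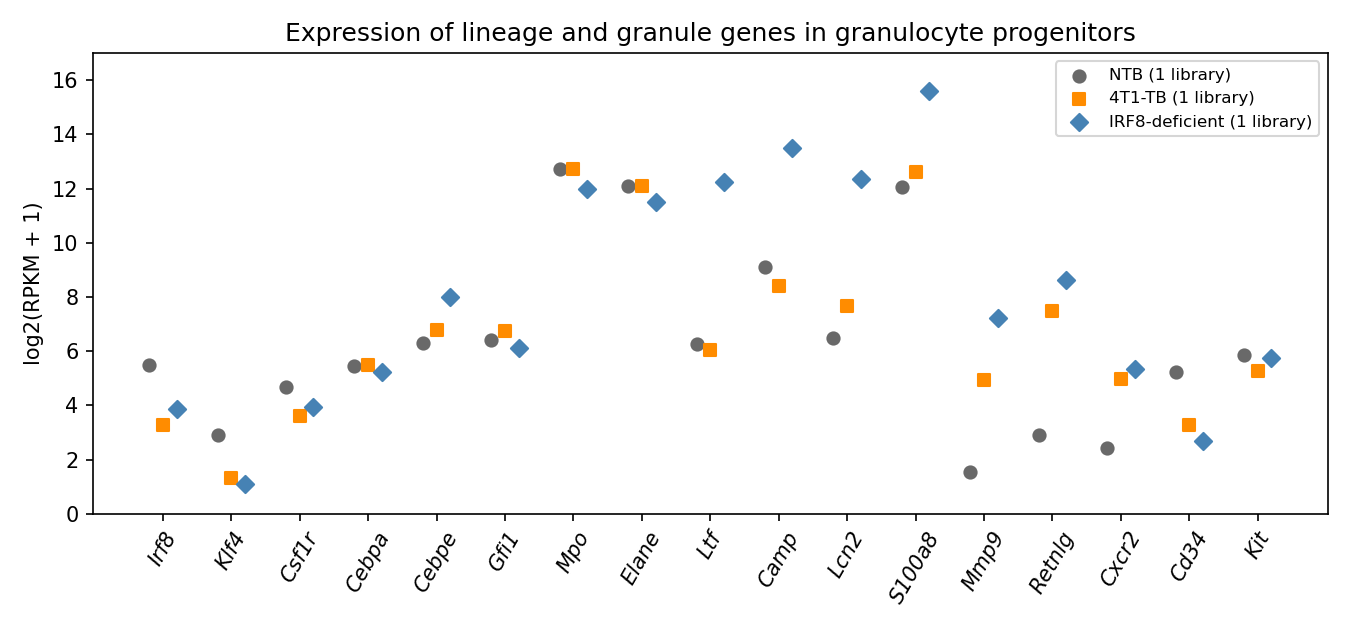
Expression, as log2(RPKM + 1), of 17 lineage, granule and surface receptor genes in the NTB (circles), 4T1-TB (squares) and IRF8-deficient (diamonds) libraries, 1 library each and so without error bars. Irf8, Klf4 and Cd34 were highest in NTB, Mpo and Elane lowest in IRF8-deficient, and Ltf, Camp, Lcn2 and S100a8 highest in IRF8-deficient.

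The first comparison, 4T1-TB with NTB, asks which genes differ between the tumor-bearing library and the control. Most genes listed for mature neutrophils were higher in 4T1-TB. Mature neutrophils left in the sort could also bring such genes, and this was not tested for 4T1-TB. Retnlg, which encodes a resistin-like secreted protein of neutrophils, had an RPKM of 178 against 6.54 (27.3-fold, interval 23.4 to 31.9). The interferon-induced membrane protein gene Ifitm1, which is also on the early progenitor list, had 73.7 against 1.28. The stefin genes Stfa2l1 and Stfa2, which encode cysteine protease inhibitors, had 32.7 against 0.054 and 22.0 against 0. Set against 3 reads in NTB, Stfa2 was 155-fold higher, and the lower limit of its interval was 125. Stfa2l1 rested on 1 read in NTB (607-fold, interval 108 to 24060). These stefin genes are related and lie near each other on chromosome 16, so their separate counts are uncertain beyond counting error. Several genes of the monocyte lineage were lower, among them Klf4, a transcription factor of monocyte differentiation (1.51 against 6.4), Ly86, a partner of a Toll-like receptor homolog (4.88 against 20.3), and Csf1r, the receptor for macrophage colony-stimulating factor (11 against 24.6).

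Of the 10658 genes compared, 178 were at least 2-fold higher and 144 at least 2-fold lower in 4T1-TB on the log2(RPKM + 1) scale. At 4-fold the counts were 47 and 5. Of 29 mature neutrophil genes, 20 were 2-fold higher and none was 2-fold lower, and the list's median difference was 1.76, above the range of random lists of like expression (−0.09 to 0.15). The secondary and tertiary granule genes, which encode proteins packed late in neutrophil maturation, split. The collagenase gene Mmp8 (36.0 against 2.45), the gelatinase gene Mmp9 (29.8 against 1.91), the surface protease gene Adam8 (6.79 against 0.458) and the chitinase-like gene Chil1 (24.5 against 8.42) were higher. Camp, which encodes the cathelicidin antimicrobial peptide, had 340.3 against 546 and Ltf, which encodes lactoferrin, 65.0 against 75.2. In total 7 of 22 were 2-fold higher and 1 was lower, with a median of 0.55 (random lists 0.01 to 0.24). No primary granule gene passed 2-fold. The serine protease gene Ctsg stood at 3617 against 2112 and Prtn3 at 4585 against 2992, Mpo at 6749 against 6811 and Elane at 4332 against 4411, and the list's median of 0.27 was inside the random range of 0.02 to 0.28.

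Of 23 monocyte and macrophage genes, 6 were 2-fold lower and none was 2-fold higher, with a median of −0.63 (random lists −0.10 to 0.17). Besides Ly86 and Klf4 these included Ms4a6c (10.4 against 33.3) and Zeb2, a repressor that acts in monocyte and dendritic cell development (10.8 against 27.0). Among 27 myeloid transcription factors, Irf8, Klf4 and Zeb2 were among 4 that were lower, Hoxa9, a factor of early progenitors, was higher (6.29 against 1.90), and the median of 0.12 lay inside the random range of −0.06 to 0.17. Cebpa, which specifies granulocyte and monocyte progenitors, stood at 43.3 against 42.6, Gfi1, a repressor needed for neutrophil development, at 105 against 84.3, Cebpe, which drives late granulocyte maturation, at 108 against 77.4, and Cebpb, which drives emergency granulopoiesis, at 19.5 against 9.79. Of 17 genes described as IRF8 targets, 3 were lower, namely Ly86, Klf4 and the survival gene Bcl2 (1.65 against 6.49), and the median of −0.08 lay inside the random range of −0.16 to 0.17. Of 11 dendritic cell and antigen presentation genes, 1 was lower, H2-DMa (6.87 against 15.8), with a median of −0.23 inside the random range (−0.27 to 0.18).

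Among genes that respond to granulocyte colony-stimulating factor and STAT3, 4 of 15 were 2-fold higher. Socs3, a feedback inhibitor of cytokine signaling, had 8.37 against 0.115 (72.9-fold, interval 43.0 to 134), the kinase gene Pim1 90.9 against 18.5, the decoy interleukin-1 receptor gene Il1r2 23.9 against 1.76 and Bcl3 9.42 against 2.53. The list's median was 0.29 (random lists −0.13 to 0.20). The receptor gene Csf3r had 119 against 79.5. Of 20 cytokine receptors, Csf2rb and Csf2rb2, which encode the shared beta chain of the GM-CSF, interleukin-3 and interleukin-5 receptors and its paralog, were higher (70.9 against 24.4 and 6.01 against 1.48), and Csf1r and Il6st were lower (11 against 24.6 and 6.37 against 16.6). That list's median was −0.17, below the random range of −0.09 to 0.19. Csf2rb and Csf2rb2 are near-identical copies, so their separate counts are uncertain.

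Of 20 effector genes of myeloid-derived suppressor cells, 3 were 2-fold higher and none lower, with a median of 0.34 (random lists −0.06 to 0.21). The mitochondrial arginase gene Arg2 had 3.88 against 0.079 and the interleukin-4 receptor gene Il4ra 27.0 against 9.52. Nos2, the inducible nitric oxide synthase, had 1.78 against 0. Set against 3 reads in NTB it was 106-fold higher, and the lower limit of its interval was 85.4. Arg1, the cytosolic arginase, was at 0.061 in 4T1-TB, from 2 reads, and listed at 0 in the other libraries. S100a8 and S100a9, which encode the calprotectin subunits, had 6254 against 4255 and 6556 against 4413.

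Of 21 cholesterol synthesis genes, 6 were 2-fold higher, with a median of 0.72 (random lists −0.16 to 0.12). Fdps, which makes farnesyl diphosphate, had 145 against 58.7, and Sqle, squalene epoxidase, 17.1 against 6.80. Of 20 unfolded protein response genes 1 was 2-fold higher, Creld2 (96.0 against 44.3), and the list's median of 0.54 lay above its random range (0.00 to 0.24). Glycolysis and hypoxia genes had a median of 0.35 (random lists −0.02 to 0.22), with the glucose transporter gene Slc2a3 at 9.93 against 2.94. Proteasome genes had a median of 0.36 (random lists 0.06 to 0.22) and oxidative phosphorylation genes 0.22 (0.08 to 0.21), and no member of either passed 2-fold. The 81 ribosomal protein genes had a median of 0.04, below their random range of 0.09 to 0.21. That median was −0.08 when libraries were rescaled without their 20 highest genes and −0.11 when scaled by summed reads.

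Immediate early genes, which are induced within minutes of stimulation, were lower in 4T1-TB for Fosb (0.239 against 11.4), Fos (13.2 against 42.5) and Jun (12.3 against 39.0), while Il1b, the interleukin-1 beta gene on the same list, was higher (10.9 against 0.168). Of 25 genes 4 were lower and 1 higher, with a median of −0.22 (random lists −0.17 to 0.10). No member of the 40 cell cycle genes passed 2-fold (median 0.09, random lists 0.05 to 0.21), and the proliferation marker Mki67 stood at 186 against 189.8. Interferon-stimulated genes had a median of −0.10 (random lists −0.21 to 0.06), with Slfn1 higher (8.75 against 0.613) and Ifi204 (0.491 against 2.25) and Slfn8 (1.61 against 4.30) lower. Apoptosis regulators had a median of 0.10 (random lists −0.13 to 0.15), with the proapoptotic gene Pmaip1 higher (3.92 against 0.673). The NADPH oxidase and antimicrobial genes had a median of 0.26 (random lists 0.00 to 0.29), with Lcn2, which encodes the siderophore-binding lipocalin, at 203 against 89.2.

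The other genes with the largest differences were Wfdc17, which encodes a small whey acidic protein domain protein (103 against 0.238), the endothelial lipase gene Lipg (54.9 against 1.08), the clusterin gene Clu (36.6 against 1.41), the acute phase gene Saa3 (14.5 against 0.168) and the metalloreductase gene Steap4 (12.3 against 0.036). Lower were Thbs1, which encodes thrombospondin 1 (0.559 against 9.86), Rasa4 (1.19 against 11.4), the interferon-inducible genes Pyhin1 (2.54 against 15.0) and Mndal (3.61 against 17.2), Cnn3 (1.24 against 7.16) and Cd34, a marker of early progenitors (8.73 against 36.9). Kit, the stem cell factor receptor, had 37.5 against 57.2. The early progenitor list as a whole, which also holds Ifitm1 and Hoxa9, had 2 of 11 members higher and 1 lower. Its median was −0.06 (random lists −0.31 to 0.16). Scaling by summed reads moved the median of all genes by −0.14 and gave 156 genes higher and 210 lower in place of 178 and 144.

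The next comparison, IRF8-deficient with NTB, asks which genes differ between the deficient library and the control. Secondary and tertiary granule genes were far higher in the deficient library. Ltf had an RPKM of 4856 against 75.2, Lcn2 5205 against 89.2 (58.4-fold, interval 56.4 to 60.4), Camp 11611 against 546 (21.3-fold, interval 20.9 to 21.6), Ngp, which encodes neutrophilic granule protein, 16528 against 632, and the chitinase-like gene Chil3 6789 against 172. Of 14 genes listed for primary granules, which mark the earlier promyelocyte stage, 2 were 2-fold lower, Nkg7 and Calr. Without passing that call, Mpo, the myeloperoxidase gene, stood at 4012 against 6811, Elane, the neutrophil elastase gene, at 2889 against 4411 and Ctsg at 1077 against 2112. The calprotectin genes S100a8 and S100a9 stood at 49180 against 4255 and 51478 against 4413.

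On the 2-fold scale 936 genes were higher and 611 lower in IRF8-deficient, and 203 and 41 at 4-fold. Of 22 secondary and tertiary granule genes 21 were 2-fold higher, with a median of 4.47 (random lists −0.30 to 0.39). Mmp9 had 149 against 1.91 and Mmp8 132 against 2.45. Of 29 mature neutrophil genes 21 were 2-fold higher, with a median of 2.16 (random lists −0.31 to 0.25), among them Retnlg (392 against 6.54), Ifitm6 (421 against 7.26), the formyl peptide receptor gene Fpr2 (103 against 1.58) and Ly6g, the neutrophil surface antigen (84.3 against 4.09). Of 14 NADPH oxidase and antimicrobial genes, a list that shares Ltf, Camp, Ngp, Lcn2 and other members with the granule list, 12 were 2-fold higher, with a median of 2.54 (random lists −0.40 to 0.56). Lyz2, which encodes lysozyme, had 8190 against 300.3. The members of the primary granule list that passed 2-fold were Nkg7 (152 against 420.4) and Calr (588 against 1183). Calr encodes calreticulin, a chaperone of the endoplasmic reticulum. The granule enzyme genes Mpo, Elane, Ctsg and Prtn3 did not pass. That list's median was −0.75 (random lists −0.39 to 0.56).

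Transcription factors differed in direction. Cebpe was higher (255 against 77.4), as were Id2 and Id1, inhibitors of basic helix-loop-helix factors (106 against 13.8 and 33.6 against 7.43), Klf5 (19.9 against 2.05) and Irf7, a regulator of type I interferon genes (6.84 against 1.07). Myc, which drives growth of progenitors, was lower (25.7 against 69.8), and so was Klf4 (1.16 against 6.4). Spi1, the PU.1 gene, had 164 against 85.5, Cebpa 36.3 against 42.6 and Gfi1 68.5 against 84.3. Of 27 factors 7 were 2-fold higher and 5 lower, with a median of 0.49 (random lists −0.28 to 0.27), which was −0.03 when libraries were scaled by summed reads. Of 17 genes described as IRF8 targets, 3 were higher and 3 lower, with a median of 0.08 (random lists −0.38 to 0.34). Ly86 (3.53 against 20.3) and Klf4 were lower, and Bcl6, a transcriptional repressor, and Fas, a death receptor, were higher (16.7 against 4.00 and 5.78 against 1.13).

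Monocyte and macrophage genes differed both ways, with 4 of 23 higher, 3 lower and a median of 0.28 inside the random range (−0.32 to 0.29). Lgals3, which encodes galectin-3, had 89.6 against 7.61 and Adgre1, the F4/80 antigen gene, 9.22 against 2.39. Of the 20 suppressor cell effector genes 8 were higher and 1 lower, with a median of 0.79 (random lists −0.35 to 0.36), led by S100a9, S100a8, Cybb, the catalytic subunit of the phagocyte oxidase (552 against 58.8), and Arg2 (2.40 against 0.079). Nos2 and Arg1 were listed at 0 in both libraries. Dendritic cell and antigen presentation genes had a median of 0.34 (random lists −0.54 to 0.44). Of 20 cytokine receptors 5 were higher and 1 lower, with a median of 0.31 (random lists −0.30 to 0.32), and Il18r1 and Il18rap, which form the interleukin-18 receptor, had 5.18 against 0.173 and 37.3 against 10.2. The G-CSF and STAT3 list had a median of 0.20 (random lists −0.34 to 0.38), with Il1r2 at 22.3 against 1.76 and Pim1 at 17.1 against 18.5.

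Of 31 interferon-stimulated genes 12 were 2-fold higher and none lower, with a median of 0.61 (random lists −0.35 to 0.19). Slfn1 had 22.8 against 0.613, and the 2'-5' oligoadenylate synthetase genes Oas3 and Oas2 had 7.74 against 0.677 and 6.28 against 0.890. The immediate early and NF-kB list had 10 members higher and 6 lower, with a median of 0.90 (random lists −0.33 to 0.26). Nfkbia, the inhibitor of NF-kB, had 75.5 against 19.1 and Tnf 16.9 against 3.88, whereas Fosb had 1.24 against 11.4, Fos 18.5 against 42.5 and Jun 12.6 against 39.0. Of 40 cell cycle genes 2 were 2-fold higher, Cenpf (41.9 against 19.2) and Nusap1 (88.9 against 42.1), and Mki67 had 368 against 189.8. Their median was 0.42 (random lists −0.18 to 0.27) and became −0.12 under scaling by summed reads. Apoptosis regulators had a median of 0.30 (random lists −0.31 to 0.28), which became −0.14 under that scaling. Replication histone genes, a list kept as a measure of library quality because most of their transcripts lack poly(A) tails, were 2-fold higher for 38 of 59, with a median of 1.15 (random lists −0.23 to 0.27), in the library with the largest share of Rn45s, so the way RNA was selected may have contributed. In 4T1-TB the Rn45s share was also above that of NTB (6.36% against 1.8%). There 0 of 59 replication histone genes were 2-fold higher than in NTB. Their median of 0.153 lay inside the random range (0.071 to 0.215). Replication histone genes are near-identical copies, and counts of single members are uncertain.

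Of 20 unfolded protein response genes 5 were 2-fold lower and 1 higher, with a median of −0.64 (random lists −0.31 to 0.39). Asns, asparagine synthetase, had 3.36 against 15.5, and the endoplasmic reticulum folding genes Pdia6 and Hyou1 had 116 against 263 and 58.9 against 125. Chac1, on the same list, had 7.73 against 0.967. The 81 ribosomal protein genes had a median of −0.43 (random lists −0.22 to 0.24) and the 74 oxidative phosphorylation genes −0.20 (−0.15 to 0.22), while the proteasome median of −0.17 (−0.20 to 0.27), the cholesterol synthesis median of −0.10 (−0.34 to 0.26) and the glycolysis median of 0.11 (−0.30 to 0.37) were inside their random ranges. Slc2a3 was higher (50.3 against 2.94). Of 11 early progenitor genes 4 were lower and 2 higher, with a median of −0.67 (random lists −0.54 to 0.44). Cd34 had 5.41 against 36.9 and Kit 53.2 against 57.2.

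Also among the largest differences, Plbd1, which encodes a phospholipase B domain protein, had 192 against 3.42. Lower were Ugt8a (0.341 against 19.7), Erdr1 (2.46 against 50.5), the inducible Hsp70 genes Hspa1b and Hspa1a (10.7 against 137 and 9.68 against 123), the adhesion gene Vcam1 (10.5 against 99.6), the receptor tyrosine kinase gene Tie1 (0.316 against 10.5), the cyclophilin gene Ppic (1.88 against 23.3) and Rab38 (0.704 against 10.6). The 2 Hsp70 genes are near-identical copies. Lars2, the mitochondrial leucyl-tRNA synthetase gene, had the largest positive difference, at 11712 against 70.2 with 2790 in 4T1-TB. Its level went with that of Rn45s, and because part of this gene is known to resemble ribosomal RNA, its count is uncertain and may include ribosomal RNA reads. Scaling by summed reads moved the median of all genes by −0.48, to −0.50, and gave 464 genes higher and 1972 lower, and rescaling without the 20 highest genes moved it by −0.16 and gave 723 and 932.

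**Figure D2:**
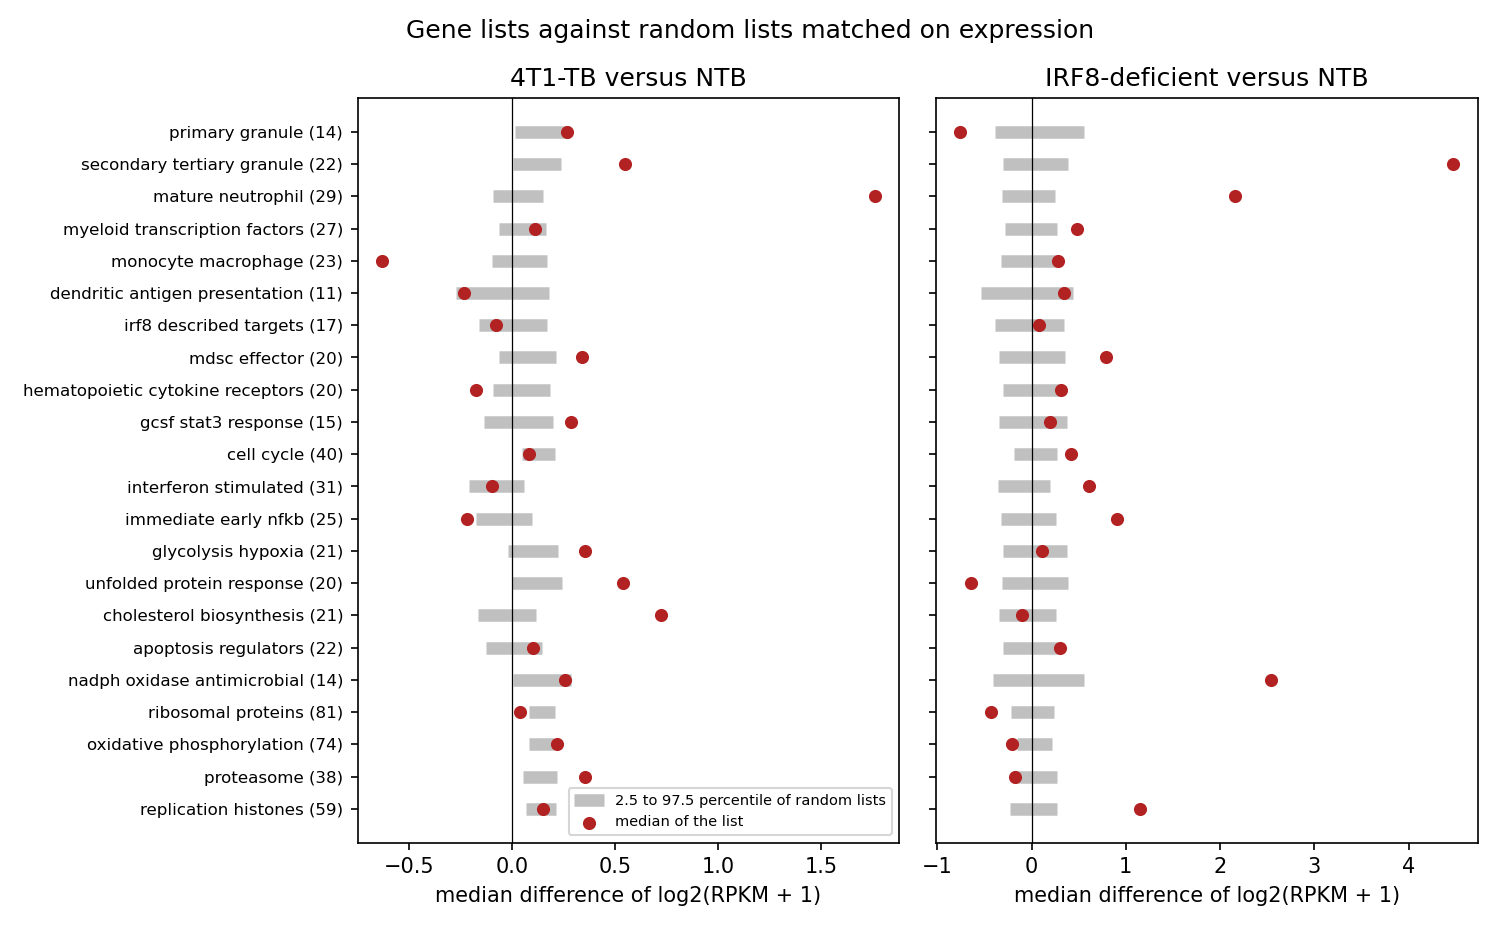
Median difference of log2(RPKM + 1) from NTB (points) for 22 gene lists in 4T1-TB (left) and IRF8-deficient (right), with the number of genes compared in brackets and bars for the central 95% of 10000 random lists matched on expression. Mature neutrophil genes lay above the bars in both panels (1.76 and 2.16), secondary and tertiary granule genes reached 4.47 in IRF8-deficient and 0.55 in 4T1-TB, and, under scaling by summed reads, medians changed sign for ribosomal proteins, cell cycle, apoptosis and transcription factors on the left and for the last 3 of these, monocyte, dendritic, IRF8 target, cytokine receptor, G-CSF and STAT3, and glycolysis lists on the right.

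Setting the libraries with low Irf8 side by side asks how far the tumor-bearing library resembled the deficient one. Over all genes 4T1-TB was no closer to IRF8-deficient than NTB was. The differences of IRF8-deficient had an SD of 0.793 against 4T1-TB and 0.791 against NTB. The counts of genes higher and lower were 941 and 754 against 4T1-TB and 936 and 611 against NTB. In both 4T1-TB and IRF8-deficient, the neutrophil genes Retnlg, Mmp8, Mmp9, Stfa2l1 and Il1r2 were higher than in NTB, as were S100a6, a calcium-binding protein gene (51.7 in 4T1-TB and 99.1 in IRF8-deficient against 4.88), the inhibitory receptor genes Lilr4b (22.1 and 23.4 against 2.30) and Lilrb4a (35.3 and 45.2 against 4.79), which are close paralogs, and the protease gene Asprv1 (12.1 and 6.35 against 0.146). The chemokine receptor gene Cxcr2, named after its values were seen, had 30.2 and 39.5 against 4.38. Lower in both were Irf8, Klf4, Ly86, Cd34, Rasa4, Fosb, Apba1 (0.747 and 0.410 against 5.28), Ly6c1, a surface antigen gene (29.4 and 28.1 against 97.9), and Hspa1a and Hspa1b. Ly6c1 is on the strain-variable list, and its more abundant paralog Ly6c2, on the same list, had 478 and 1349 against 739.

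In all, 104 genes were 2-fold higher in both and 51 were 2-fold lower in both, while 4 were higher in 4T1-TB and lower in IRF8-deficient and 13 the reverse. Independent lists of these sizes would share 15.6, 8.3, 10.2 and 12.6. Under scaling by summed reads 82 were higher and 105 lower in both. Of the 178 genes higher in 4T1-TB, 145 were also above NTB in IRF8-deficient at any size, and of the 144 lower genes 114 were below it. Across genes, which are not independent replicates, the differences from NTB had a Pearson r of 0.267 and a covariance of 0.0913. Both comparisons used the same NTB library, and unchanged libraries simulated with an assumed biological coefficient of variation gave a covariance of 0.0022 at 0, 0.0187 at 0.1, 0.0689 at 0.2, 0.107 at 0.25, 0.155 at 0.3 and 0.278 at 0.4, with r between 0.345 and 0.5. The simulated numbers of genes higher and lower in both were 6.2 and 3.0 at 0.2, 39.2 and 23.4 at 0.25, 108.6 and 67.0 at 0.3 and 342.6 and 246.8 at 0.4. The simulated numbers higher and lower in 4T1-TB, where 178 and 144 were observed, were 45.9 and 47.0 at 0.2, 174.4 and 179.9 at 0.25, 384.5 and 390.0 at 0.3 and 918.1 and 920.8 at 0.4. Every simulated library had the same variation, unlike the real ones. The part of the variance across genes that belonged to 1 library alone was 0.0913 for NTB, which is the covariance above. It was 0.0954 for 4T1-TB and 0.534 for IRF8-deficient. The simulated numbers of shared genes are therefore no matched expectation for these libraries. The true variation between animals is unknown and 1 control library cannot be split. Part or all of the overlap may thus come from the shared control.

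**Figure D3:**
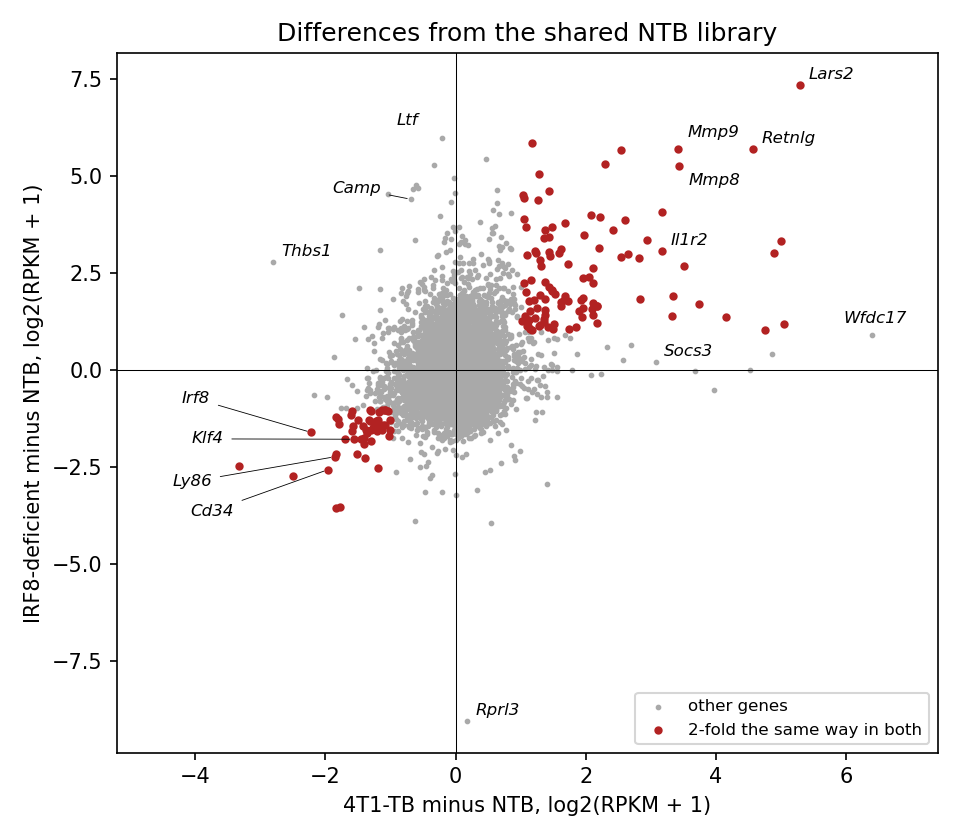
Difference from the NTB library in log2(RPKM + 1) for 10658 genes, in 4T1-TB (horizontal) and in IRF8-deficient (vertical), 1 point per gene, with the 104 genes higher and 51 lower in both by 2-fold in red. Irf8, Klf4, Ly86 and Cd34 lay low on both axes, Retnlg, Mmp8 and Mmp9 high on both, Ltf and Camp high on the vertical axis alone, and Thbs1 low in 4T1-TB and high in IRF8-deficient; NTB values enter both axes.

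The last comparison, IRF8-deficient with 4T1-TB, asks where the 2 settings of low Irf8 part. Secondary granule genes separated them most. Ltf had 4856 in IRF8-deficient against 65.0 in 4T1-TB, Chil3 6789 against 136, Olfm4, which encodes olfactomedin 4, 189 against 3.02, Lyz2 8190 against 197, Ngp 16528 against 424 and Camp 11611 against 340.3. Thbs1 had 73.7 against 0.559, the ganglioside synthase gene St3gal5 51.1 against 0.661, and Lyz1, a lysozyme paralog, 743 against 17.7. Higher in 4T1-TB were Wfdc17 (103 against 1.31), Clu (36.6 against 0.678), Ifitm1 (73.7 against 4.24), Lipg (54.9 against 3.31), Steap4 (12.3 against 0.024), Socs3 (8.37 against 0.281) and Stfa2 (22.0 against 0).

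Here 941 genes were higher and 754 lower in IRF8-deficient. Of 22 secondary and tertiary granule genes 20 were higher, with a median of 3.42 (random lists −0.40 to 0.32), and of 14 primary granule genes 7 were lower and 1 higher, with a median of −0.94 (−0.52 to 0.43). Mature neutrophil genes divided, with 11 of 29 higher, 7 lower and a median of 0.62 (−0.32 to 0.28). The stefin genes Stfa2 and BC100530 (27.9 in 4T1-TB against 0.347) and Ifitm1 were among the lower ones, and Ly6g (84.3 against 8.16) among the higher ones. The NADPH oxidase and antimicrobial median was 1.94 (−0.51 to 0.43).

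Monocyte and macrophage genes were higher in IRF8-deficient than in 4T1-TB for 10 of 23 and lower for 1, with a median of 0.78 (random lists −0.34 to 0.31). Mpeg1, which encodes perforin-2, had 109 against 24.3 and Ccr2, the chemokine receptor of inflammatory monocytes, 40.8 against 13.4. Interferon-stimulated genes had a median of 0.85 (−0.28 to 0.29) with 11 of 31 higher, and the immediate early and NF-kB list 0.87 (−0.29 to 0.33) with 11 of 25 higher and 1 lower. Medians were 0.83 for dendritic cell and antigen presentation genes (−0.48 to 0.52), 0.43 for suppressor cell effectors (−0.40 to 0.34), 0.49 for cytokine receptors (−0.36 to 0.32), and 0.45 for myeloid transcription factors (−0.33 to 0.27), and 1.04 for the replication histones of the library quality lists (−0.33 to 0.16). IRF8 target genes (0.22), apoptosis regulators (0.28), the G-CSF and STAT3 list (−0.22) and early progenitor genes (−0.43) lay inside their random ranges. Cell cycle genes had a median of 0.26 (−0.31 to 0.20), which became −0.13 under scaling by summed reads.

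Of 20 unfolded protein response genes 11 were lower and 1 higher in IRF8-deficient than in 4T1-TB, with a median of −1.12 (random lists −0.42 to 0.32), and Asns had 3.36 against 28.9 and Sdf2l1 51.2 against 198. Of 21 cholesterol synthesis genes 8 were lower, with a median of −0.68 (−0.32 to 0.33), and Sqle had 2.19 against 17.1. Ribosomal protein (−0.48), oxidative phosphorylation (−0.42), proteasome (−0.42) and glycolysis (−0.41) medians also lay below their random ranges. Scaling by summed reads moved the median of all genes by −0.33 and gave 505 genes higher and 1573 lower.

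Markers of other cells that bone marrow or a tumor could supply were mostly low. No T and NK cell gene and no Y-linked gene reached an RPKM of 1. Among B cell genes Cd79b had 16.4 in NTB, 12.3 in 4T1-TB and 10.3 in IRF8-deficient. Of erythroid genes Car2, carbonic anhydrase 2, had 4.25, 2.62 and 0.214 and Blvrb 2.93, 1.81 and 7.29 in the same order. Basophil and mast cell genes had a median of −0.75 in IRF8-deficient against NTB (random lists −0.74 to 0.78), with the histidine decarboxylase gene Hdc at 104, 61.4 and 54.5. Mcpt8, on the same list, had 15.7, 20.4 and 8.73. Eosinophil medians lay inside their random ranges in every comparison, as did those of megakaryocyte genes, and the eosinophil-associated ribonuclease gene Ear2 had 0.249, 0.189 and 24.1. Siglecf, also on the eosinophil list, had 12.9, 12.1 and 9.86. Among stromal and endothelial genes Pecam1 had 12, 5.77 and 6.28, and among epithelial genes Krt18, a keratin gene, had 5.93, 2.03 and 0.219, so that the keratin was lower in the tumor-bearing library than in NTB.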

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

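The tests under scaling by summed reads, thinning to equal depth and a counting interval were chosen after the data were seen. No paired analysis was possible because each group had 1 library. Under median ratio scaling, thinning and the counting interval, every count, Irf8 difference and covariance that was computed stayed within 1.5 times its main count or within counting error. Over all settings the median of the secondary and tertiary granule list stayed between 3.94 and 4.70 in IRF8-deficient against NTB, that of mature neutrophil genes between 1.06 and 2.63 in 4T1-TB and between 1.53 and 2.71 in IRF8-deficient, and that of monocyte genes between −0.78 and −0.41 in 4T1-TB. In IRF8-deficient the monocyte median ran from −0.26 to 0.34. The megakaryocyte list had too few members at an RPKM of at least 5 and gave no value there. Low genes rest on few reads, and 4T1-TB had the fewest reads of the libraries. Thinning to equal depth gave 181 genes higher and 144 lower in 4T1-TB than in NTB, where the main counts were 178 and 144. Except where the setting itself fixes the outcome (a stricter call or filter leaves fewer genes, and a larger pseudocount shrinks differences), the cause was not tested.

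With a pseudocount of 0.1, 4T1-TB against NTB had 282 genes higher and 354 lower, IRF8-deficient against NTB had 1071 lower, 173 were higher and 138 lower in both, the Irf8 difference in 4T1-TB was −2.33 and the covariance 0.195. With a pseudocount of 5 the counts higher and lower were 65 and 21 for 4T1-TB, 526 and 149 for IRF8-deficient against NTB and 475 and 311 against 4T1-TB, with 38 higher and 10 lower in both, Irf8 differences of −1.84 and −1.38 and a covariance of 0.0358. With no filter the covariance was 0.0434. With an RPKM of at least 5, 4T1-TB had 115 genes higher and 74 lower, and 27 were lower in both. At 4-fold the counts were 47 and 5, 203 and 41, and 178 and 50, with 23 higher and 2 lower in both. Rescaled without the 20 highest genes, IRF8-deficient had 932 genes below NTB, Irf8 differences were −2.34 and −1.78, and the ribosomal protein median in 4T1-TB turned to −0.076.

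Scaled by summed reads, IRF8-deficient had 464 genes higher and 1972 lower than NTB and 505 higher and 1573 lower than 4T1-TB, 82 genes were higher and 105 lower in both, and Irf8 differences were −2.38 and −2.12. Among lists outside their random ranges, the IRF8-deficient medians against NTB of transcription factors (−0.030), cell cycle genes (−0.12) and apoptosis regulators (−0.14) turned negative, as did cell cycle genes against 4T1-TB (−0.13) and ribosomal proteins in 4T1-TB against NTB (−0.11). Several medians inside their random ranges also changed sign under this scaling and without the 20 highest genes. Scaling by summed reads lowers every IRF8-deficient value by 1 common factor, and the median of all genes moved by −0.48 against NTB, to −0.50. Besides the reversals given, 63 of 81 list medians moved by 1 SD of random lists or more under scaling by summed reads and 33 did without the 20 highest genes, some of them changing sign. Over all settings the IRF8-deficient medians against NTB ran from 0.26 to 0.82 for suppressor cell effectors, 0.22 to 0.77 for interferon-stimulated genes and 0.31 to 0.99 for immediate early genes. Against 4T1-TB they ran from 0.10 to 1.09 for dendritic cell and antigen presentation genes, 0.05 to 0.77 for suppressor cell effectors, 0.11 to 0.50 for cytokine receptors and 0.09 to 0.48 for transcription factors.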

Other observations

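All tests of explanations in this part were chosen after the results were seen. Small sets of genes stood well above background in 1 library only, and they are named because of their values. With an RPKM of at least 5 in 4T1-TB and under 0.5 in the others were 4 genes, Socs3, Steap4 and the stefin genes Stfa2 and BC100530. In IRF8-deficient 11 genes showed that pattern, among them Penk, which encodes the enkephalin precursor (18.9 against 0.253 in NTB), the tight junction gene Cldn1 (14.7 against 0.351), Ear2 (24.1 against 0.249), Il18r1 (5.18 against 0.173) and Nt5e, which encodes the adenosine-producing ectoenzyme CD73 (5.08 against 0.225). No gene did so in NTB. Among the stefin genes, whose separate counts are uncertain, Stfa2l1 had 9.62 in IRF8-deficient.

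Of 8 strain-variable genes compared, 3 were 2-fold higher and 3 lower in IRF8-deficient than in NTB, and 2 were lower in 4T1-TB than in NTB, which is of the same strain. The class I genes H2-K1 and H2-D1 had an RPKM of 439.6 and 244 in IRF8-deficient against 133 and 94.3 in NTB and 137 and 105 in 4T1-TB. Trim12a had 28 against 7.70 in NTB, Nlrp1b 0.143 against 1.99, and Ifi202b was listed at 0 against 3.80 in NTB and 0.827 in 4T1-TB. The list's median was 0.30 against NTB (random lists −0.50 to 0.60), 0.61 against 4T1-TB (−0.56 to 0.56) and −0.30 between the F1 libraries (−0.14 to 0.30).

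Rn45s had an RPKM of 2903 in NTB, 11417 in 4T1-TB and 32498 in IRF8-deficient.

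The first pattern weighed is the higher level of secondary and tertiary granule genes in IRF8-deficient. The scale of that library, which is rich in ribosomal RNA, is argued against, since the list's median stayed at 3.94 or more under every scaling. Added mature neutrophils that no longer divide could lower division genes against genes of like expression. The cell cycle median of 0.42 lay above its random range (−0.18 to 0.27). That result cannot decide, because a small share of such cells may shift division genes little, and the random lists come from the same library. Such cells could still account for part or all of the granule genes. Earlier forms of this test were the lowest median over the scalings, −0.12, and that less the median of all genes, 0.384. They were set aside, because a scaling moves every gene of a library alike. The sort selected granulocyte progenitors, with gates not given in the sources used here, and the neutrophils' abundant transcripts S100a8 and S100a9 stood at 49180 and 51478. Strain cannot be told apart from genotype, as the median was 3.42 against the F1 4T1-TB library too and no C57BL/6 library with IRF8 was analysed here; later-stage dividing progenitors in the gate and IRF8 deficiency itself remain open and untested.

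The second pattern is that Fos, Fosb, Jun, Hspa1a and Hspa1b were lower in both 4T1-TB and IRF8-deficient than in NTB. A stronger response to handling in the NTB cells is a candidate explanation. The test was first made on the whole immediate early list (median −0.22 in 4T1-TB and 0.90 in IRF8-deficient), but Fos, Fosb and Jun had raised the pattern, so they were then left out. For 4T1-TB the other 22 immediate early genes had a median of −0.16, inside their random range (−0.18 to 0.11), and for IRF8-deficient 0.97, above theirs (−0.35 to 0.26) and opposite to what handling predicts, with 10 members higher and 3 lower, on a list that also holds NF-kB genes, so neither test supports it and it is not excluded. A biological difference in stress signaling stays open in both, and handling was not recorded in the sources used here.

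The third pattern is 7 genes under an RPKM of 0.5 in IRF8-deficient and at least 5 in both other libraries, namely Ugt8a, Tie1, Smo, Fah, Gstm5, AI506816 and Rprl3. At the mean level of the F1 libraries at least 145.8 reads were expected for each, where Gstm5 had 11 and Ugt8a 32. The limits that picked these genes made such a gap nearly certain, so it is no separate test of depth. The read numbers show only that few reads were seen where many were expected. Rprl3 (0.162 against 610 in NTB, 1 read against 6476) is a ribozyme RNA gene with a near-identical relative, Rpph1 (18696 against 10186), so its count is uncertain. A strain difference between F1 and C57BL/6 mice could give such a set and cannot be told apart from genotype, because they changed together. The same pattern was shown by 0 genes in 4T1-TB and by 6 in NTB, namely Adam8, Asprv1, Fpr1, Stfa2l1, Mir6236 and Mir6240, and neither number bears on what C57BL/6 mice would show.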
